A study of Homo sapiens with 12 samples.

How the data were processed

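RNA was measured by sequencing of poly(A) RNA in 12 samples of 2 cell lines, labelled Huh7 and HepG2, left untreated or treated with geniposide for 48 h, with 3 samples in each of the 4 groups. Per the labels' protocols, mRNA was captured with poly-T oligonucleotides, primed with random hexamers and made into cDNA libraries with ligated adaptors, and nothing in the protocol marks the strand of the RNA. Fragments from a gene and from an overlapping gene on the opposite strand can therefore not be told apart. Per the submitters' processing notes, CASAVA and fastp were used and the genome build was hg38. Their versions, the aligner and the counting program are not given in the sources used here. The labels do not say whether the 3 samples of a group came from separate cultures. The p-values then measure only the spread between these samples, which may be technical.

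The deposited table holds FPKM (fragments per kilobase of gene, scaled to the size of the library) for 58735 genes in 12 columns, and each column was matched to its sample by name, with 0 columns left over. FPKM was computed by the authors before deposit and was not recalculated. All 58735 gene identifiers were found in GENCODE 29, and 58690 genes had the coordinates of that release, so lengths, biotypes and positions were used as the table gives them. FPKM multiplied by gene length came out as whole multiples of a per-library step for 100% of values within 0.05 fragments, which gave the number of fragments per gene. These summed to between 15056655 and 17211659 fragments per library. The total by which the authors divided was 0.895 to 1.17 times the recovered sum, and how it was made is not given in the sources used here. A gene with 0 fragments can hold up to 3 fragments' worth of signal by counting error, which in a gene of 1 kb is 0.161 to 0.212 FPKM. Floors of this kind cover counting error only, because fragments without molecular identifiers are not independent molecules. No pair of libraries in a group agreed within sampling noise (lowest chi-square per degree of freedom 2.29), so each was counted as a sample.

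Changes were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1). A single model with 4 group means was fitted to the 12 samples, with 8 residual degrees of freedom, moderated variances with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05 within each comparison. A fold change on the log2(FPKM + 1) scale understates the change of genes near or under 1 FPKM. Genes needed 1 FPKM or more in at least 3 of the 12 samples, which left 15518 genes, 12150 of them protein-coding. A gene below that filter was taken from the same model without the filter. The comparisons were geniposide against untreated in each line, the difference between the effects in both lines, and the untreated lines against each other. Overlap between the lines was set against the number expected of independent lists, with a one-sided Fisher's exact test per direction. The lines have separate untreated samples, so no control library is shared.

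Gene lists were tested with limma's camera at a preset correlation of 0.01 between genes, with adjustment over the lists, and again with an estimated correlation and with fry. There were 47 lists with 1095 symbols, of which 1093 were found in the table, 46 of them through older symbols. The 42 lists with at least 5 tested members were tested. They cover ferroptosis and redox defence, stress responses, lipid and sugar metabolism, the cell cycle, mitochondria and ribosomes, signalling, liver identity, and markers of other cell types. The design, the lists, the rule for named genes and most alternatives were fixed before the data were examined.

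The genes named in the text follow a rule. For each treatment comparison it takes the 10 largest rises and the 10 largest falls among protein-coding genes past the threshold, with all 3 treated values on the same side of all 3 untreated values and a higher group mean of at least 2 FPKM. It takes the 5 largest in each direction for the difference between lines and for the untreated lines, and up to 10 genes changed the same way in both lines by the larger p-value. It always takes DUOX1, DUOXA1, DUOX2, DUOXA2, NOX4, GPX4, SLC7A11, ACSL4, AIFM2, FTH1, FTL, TFRC, NCOA4, HMOX1, CHAC1, PTGS2 and GLP1R. From each list that passed camera or holds at least 3 changed genes it takes up to 4 changed members with the smallest p-values. Y-linked genes and XIST were left out. Genes named outside the rule are said to be so, and some genes that the rule takes are not reported here.

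The fitting steps were tested on simulated data made from each gene's mean level over all libraries of a line. Each gene had a single spread averaged over the 4 groups, so a wider spread in 1 group was evened out. In 10 runs with 200 changed genes each, among 15401 to 15422 genes in the fit, the Huh7 comparison recovered 56.0% of genes changed 1.5-fold and 81.1% of those changed 2-fold. The HepG2 comparison recovered 54.7% and 78.2%. Of the calls, 10.2% (Huh7) and 13.6% (HepG2) were unchanged genes, above the share of 0.05 that the adjustment aims at, so single calls near the threshold are less certain than their adjusted p. These shares and the recovery depend on the simulated setting and need not hold for the real data. There 5357 (Huh7) and 6602 (HepG2) genes were called, far more than the 200 changed here. A planted list was called in 10 of 10 runs, with 0 other lists called. The simulated genes varied independently of each other, whereas the correlation estimated in the real data was 0.543 for the ATF4 targets. These list counts therefore do not show how the list test behaves with correlated genes.

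Alternatives were a pseudocount of 0.1 FPKM, no filter, a filter of 5 FPKM, 3 rescalings (columns brought to the same sum as TPM, median-of-ratios factors, quantile normalization), a fit within each line, no intensity trend, sample weights, the replicate number as a block, a minimum change of 2-fold, and each library left out in turn. Added after the data were seen were voom on the recovered fragments, the recovered fragment sum as denominator, and the lists without the third treated Huh7-labelled library. The rescalings were first run with the filter applied afterwards. Once those results were seen, the filter was kept on the deposited FPKM, and the first version was retained for TPM as a further alternative. Tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.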

Results

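Transcript levels were measured in 12 samples labelled as 2 human liver tumour lines. Huh7 is a line from a hepatocellular carcinoma, and HepG2 is a hepatoblastoma line often used as a hepatocyte model. Each line was left untreated or given geniposide, an iridoid glycoside of gardenia fruit, for 48 h, with 3 samples per group. By its title the study asked whether geniposide acts through DUOX1, a membrane oxidase that makes hydrogen peroxide, and through ferroptosis, a cell death driven by iron-dependent lipid peroxidation. The libraries held 15056655 to 17211659 fragments assigned to genes. Levels are given as mean ± SD of the deposited FPKM over n = 3 libraries, and changes as the limma difference in log2(FPKM + 1) ± SE with its adjusted p. Groups carry the names on the labels, because most transcripts of proteins that liver cells secrete were near 0 in every library.

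ALB, which encodes serum albumin, had 6 fragments over the 12 libraries together, the retinol and thyroxine carrier TTR had 3, the fetal serum protein AFP had 2, and APOB, the core protein of liver lipoproteins, had 0. Of 34 secreted hepatocyte proteins, 3 reached 1 FPKM in the untreated libraries of either line. These were APOE at 1.5 FPKM in the Huh7-labelled libraries, and VTN at 4.78 and complement C3 at 27.5 FPKM in the HepG2-labelled libraries. The median level that 3 fragments give over this list was 0.0622 FPKM. With geniposide all 3 of the secreted proteins rose in HepG2-labelled libraries (3 adjusted over the list alone), VTN to 7.94 FPKM (adjusted p = 0.000275, but 0.1 with a pseudocount of 0.1 FPKM), C3 to 40.4 FPKM (adjusted p = 0.0054) and APOE from 0.0942 to 0.669 FPKM (0.61, adjusted p = 0.000923, and 1.37 with TPM scaling). In Huh7-labelled libraries C3 rose from 0.786 ± 0.0417 to 1.5 ± 0.517 FPKM (adjusted p = 0.0156), and no other did. The hepatocyte transcription factor HNF4A stood at 0.0164 and 0.252 FPKM in untreated Huh7-labelled and HepG2-labelled libraries, below its 3-fragment level of 0.0256 FPKM in the former. Of 20 such factors 8 reached 1 FPKM, among them CEBPB (19.8 and 116 FPKM) and ESRRA (17.9 and 33.7 FPKM). Of 18 fetal and tumour liver genes 12 did so, including GPC3 at 26.3 FPKM in the Huh7-labelled libraries and 0 in the others. Markers of other cell types at 1 FPKM or more numbered 2 of 14 for leukocytes, 1 of 10 for endothelium, 4 of 10 for cholangiocytes (KRT7, KRT19, SOX9 and MUC1) and 7 of 12 for fibroblasts.

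**Figure D1:**
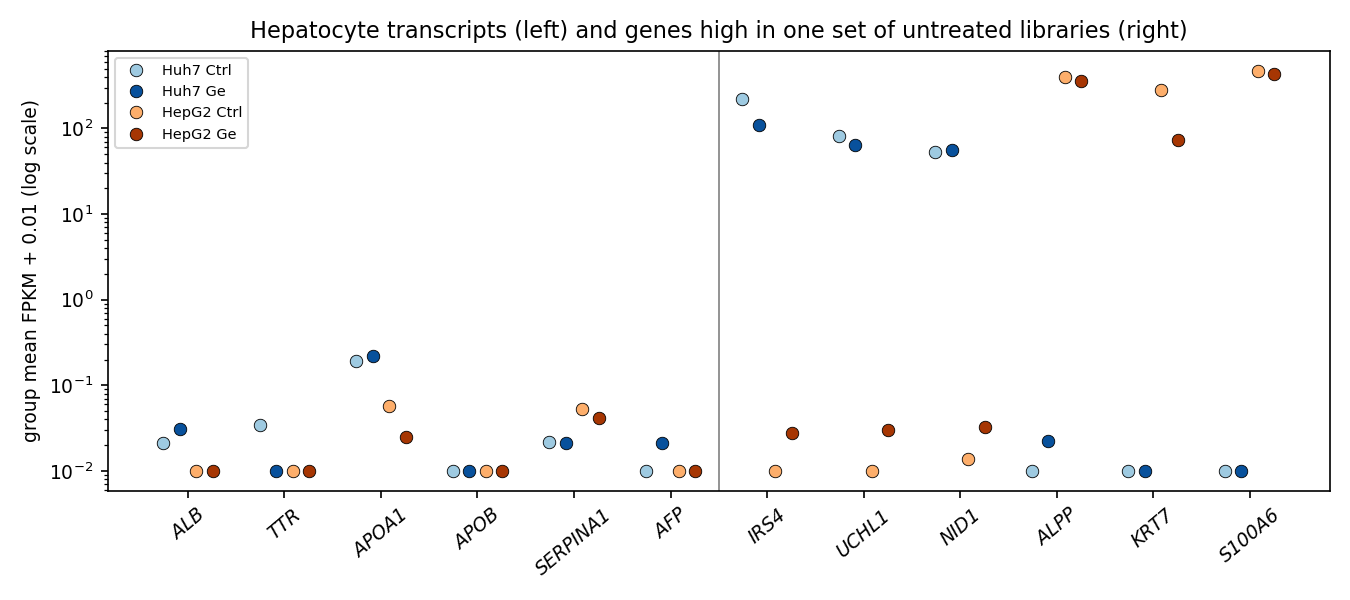
Mean FPKM of the 3 libraries in each of the 4 groups, with 0.01 added so that 0 can be drawn on a log axis, for 6 transcripts of liver cells (ALB, TTR, APOA1, APOB, SERPINA1, AFP) and 6 that were high in the libraries of either label (IRS4, UCHL1, NID1, ALPP, KRT7, S100A6). The liver transcripts sit near the bottom of the axis in all groups, while ALPP reaches 394 FPKM in untreated HepG2-labelled libraries and IRS4 reaches 219 FPKM in untreated Huh7-labelled libraries.

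DUOX1 was low in all libraries and higher with geniposide in both lines. In Huh7-labelled libraries it rose from 0.0921 ± 0.00584 to 0.307 ± 0.0685 FPKM, and in HepG2-labelled libraries from 0.254 ± 0.0540 to 0.790 ± 0.0926 FPKM. These levels rest on 13, 14 and 14 fragments against 41, 59 and 47 in Huh7-labelled libraries, and on 35, 26 and 38 against 115, 94 and 99 in HepG2-labelled libraries. All treated values lay above all untreated values of the same line, and the ratios of the means were 3.33 and 3.11. The gene (ENSG00000137857) lies on the plus strand of chromosome 15 from 45129933 to 45165576 in hg38, and its start overlaps the start of DUOXA1, which is transcribed from the other strand. On the log2 scale the changes were 0.26 ± 0.06 (95% confidence interval 0.12 to 0.40, adjusted p = 0.0225) and 0.51 ± 0.06 (0.37 to 0.65, adjusted p = 0.000322) in the fit without a filter, since DUOX1 fails the filter of 1 FPKM. At so low a level these changes depend on the pseudocount: they were 1.07 and 1.34 with 0.1 FPKM added in place of 1, 0.74 and 1.02 with TPM scaling, and 1.67 and 1.64 with voom on the recovered fragments. The difference between the lines was 0.25 ± 0.09 (adjusted p = 0.116). The call in Huh7-labelled libraries ended when any of untreated libraries 1, 2 or 3 or treated library 2 was left out (adjusted p 0.0647 to 0.0697). The share of fragments in lncRNAs moved with treatment too, from 1.71 to 1.77% to 1.88 to 2.08% in Huh7-labelled and from 1.12 to 1.18% to 1.48 to 1.51% in HepG2-labelled libraries. The study may have chosen DUOX1 on these samples, so its direction here is not independent evidence.

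Of 17 oxidase complex genes 4 passed the filter of 1 FPKM, too few for a set test. NOXA1, an activator of NADPH oxidases, rose from 4.36 ± 0.156 to 8.01 ± 0.265 FPKM in Huh7-labelled libraries and from 5.25 ± 0.517 to 8.15 ± 0.648 FPKM in HepG2-labelled libraries (adjusted p = 3.78e-05 and 0.00013). The membrane subunit CYBA fell in both, by 0.36 and by 0.28 on the log2 scale (adjusted p = 0.000455 and 0.00157). The GTPase RAC2 fell in HepG2-labelled libraries from 1.96 to 1.11 FPKM (adjusted p = 0.00753). These calls, 1 rise and 1 fall in Huh7-labelled and 1 rise and 2 falls in HepG2-labelled libraries, also passed adjusted over the list alone. DUOX2, the closest relative of DUOX1, rose in HepG2-labelled libraries from 0.0664 ± 0.00458 to 0.177 ± 0.0272 FPKM (adjusted p = 0.00312), and in Huh7-labelled libraries it changed by 0.01 ± 0.03 (adjusted p = 0.827). The maturation factors DUOXA1 and DUOXA2 were at 0.117 FPKM or less in every group mean, with adjusted p between 0.413 and 0.807. NOX4 was listed at 0 in all groups but treated HepG2-labelled libraries (0.00374 FPKM), and the incretin receptor GLP1R, proposed elsewhere as a target of geniposide, reached 0.0173 FPKM at most.

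Among the fixed ferroptosis genes, the cystine transporter SLC7A11 and the glutathione-degrading enzyme CHAC1 rose in Huh7-labelled libraries, while the prostaglandin synthase PTGS2, a common transcript marker of ferroptosis, rose in HepG2-labelled libraries. SLC7A11 went from 6.17 ± 0.620 to 22.3 ± 9.90 FPKM in Huh7-labelled libraries (1.63 ± 0.21, adjusted p = 0.000252). In HepG2-labelled libraries it was 4.65 ± 0.131 and 3.04 ± 0.225 FPKM (adjusted p = 0.0922, and 0.000170 without the third treated Huh7-labelled library, which adds to the shared spread). CHAC1 was at 1.08 and 0.470 FPKM there (adjusted p = 0.279, and 0.0384 in a fit of that line alone). PTGS2 went from 3.53 ± 0.216 to 19 ± 1.96 FPKM in HepG2-labelled libraries (2.14 ± 0.09, adjusted p = 1.01e-07), and in Huh7-labelled libraries it was 0.101 and 0.192 FPKM (adjusted p = 0.395). GPX4, which reduces lipid peroxides, was at 194 ± 3.45 and 181 ± 30.3 FPKM in Huh7-labelled libraries (−0.11 ± 0.10, adjusted p = 0.445) and at 97.2 ± 2.04 and 103 ± 8.24 FPKM in HepG2-labelled libraries (0.08 ± 0.10, adjusted p = 0.607). ACSL4, which loads polyunsaturated fatty acids into lipids, fell by 0.34 ± 0.05 in Huh7-labelled libraries (adjusted p = 0.000553) and rose by 0.20 ± 0.05 in HepG2-labelled libraries (adjusted p = 0.00832). The transferrin receptor TFRC fell in both, from 36.2 to 22.7 FPKM (adjusted p = 0.00496, but 0.0685 in a fit of that line alone) and from 127 to 80.2 FPKM (adjusted p = 0.00491). The ferritin heavy chain FTH1 rose in HepG2-labelled libraries from 1535 ± 48.2 to 2159 ± 159 FPKM (adjusted p = 0.000207). Its change of 0.18 in Huh7-labelled libraries had an adjusted p of 0.0587, and passed with TPM scaling (0.26, adjusted p = 0.00789), with other scalings, and without treated Huh7-labelled library 1 (adjusted p = 0.0452) or treated HepG2-labelled library 3 (adjusted p = 0.035). The ferritin light chain FTL fell by 0.24 in HepG2-labelled libraries (adjusted p = 0.0222), a call lost with no filter (adjusted p = 0.168), with quantile normalization (adjusted p = 0.579) and with other settings, and when HepG2-labelled untreated library 1 or 2, or treated library 1 or 2, was left out (adjusted p 0.0630 to 0.0842). HMOX1, which frees iron from haem, was at 24.6 ± 1.07 and 16.6 ± 14.2 FPKM in Huh7-labelled libraries (adjusted p = 0.124), with treated libraries at 8.36, 8.52 and 33.0 FPKM. Without the third treated library HMOX1 fell by 1.44 (adjusted p = 2.80e-07). In HepG2-labelled libraries it was at 13.9 and 11 FPKM (adjusted p = 0.572, and 0.000672 without that library). AIFM2 and NCOA4 did not pass in either line, but AIFM2 passed in HepG2-labelled libraries in a fit of that line alone (0.15, adjusted p = 0.00771).

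**Figure D2:**
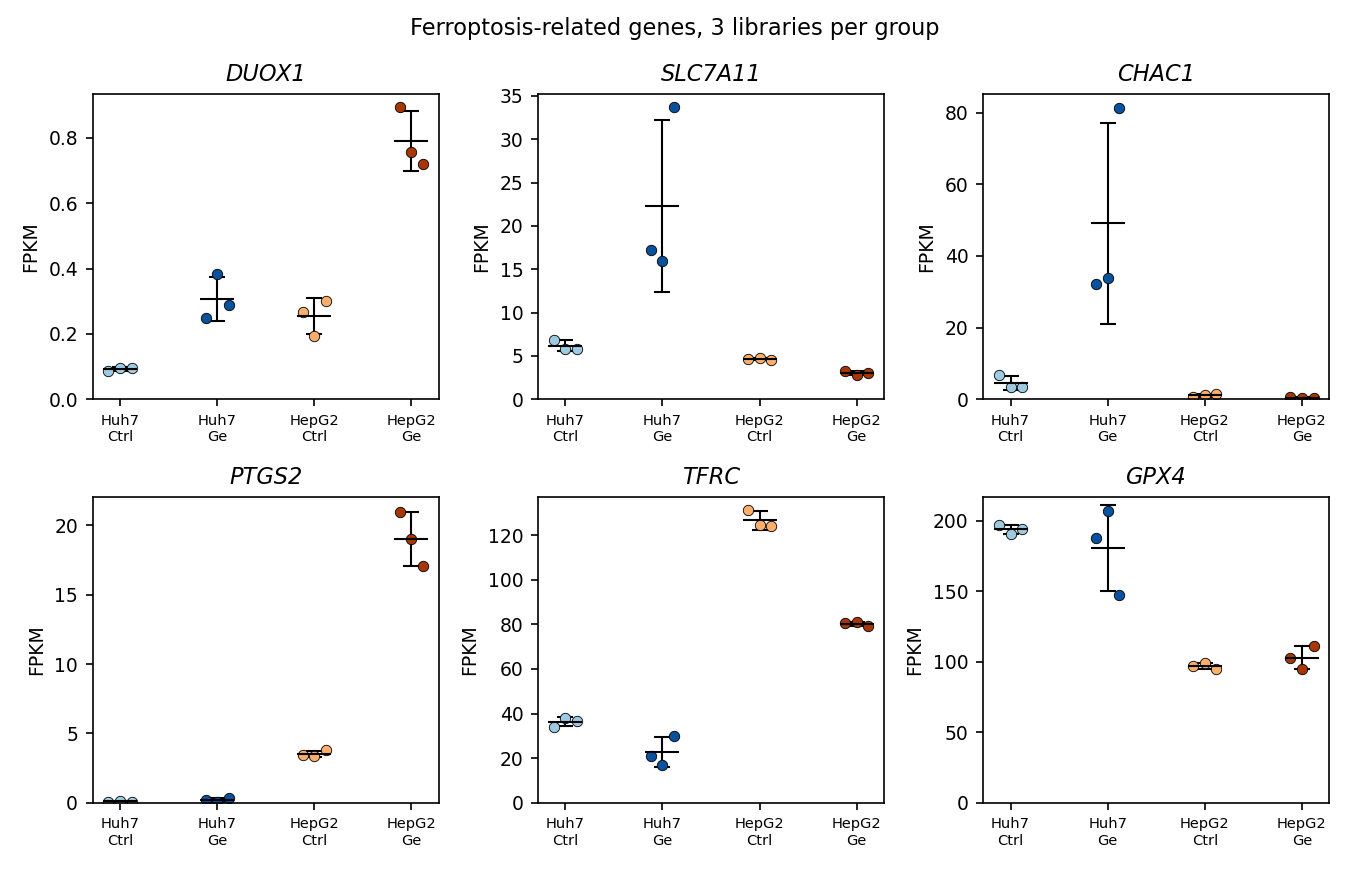
FPKM per library (points) with the mean and SD of each group (n = 3) for DUOX1, SLC7A11, CHAC1, PTGS2, TFRC and GPX4, in untreated and geniposide-treated libraries of each label. DUOX1 is higher with geniposide under both labels and stays below 1 FPKM, SLC7A11 and CHAC1 are higher in treated Huh7-labelled libraries, and PTGS2 is higher in treated HepG2-labelled libraries.

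Of the ferroptosis lists, the transcript markers passed camera in Huh7-labelled libraries and the restraining genes in HepG2-labelled libraries, and neither held with an estimated correlation. Of 27 tested genes that restrain ferroptosis, 4 rose and 6 fell in Huh7-labelled libraries (4 and 6 adjusted over the list alone; camera adjusted p = 0.540). In HepG2-labelled libraries 2 rose and 12 fell (2 and 13 adjusted over the list alone). Their median was −0.24 (camera adjusted p = 0.0298, adjusted p = 0.231 with an estimated correlation). Quantile normalization ended that call (adjusted p = 0.0695). Members that fell there were the glutathione reductase GSR, from 27.0 ± 0.730 to 15.5 ± 1.59 FPKM, the glutathione synthetase GSS, from 13.3 to 7.93 FPKM, and the peroxiredoxin PRDX6, from 191 to 132 FPKM. Of 26 genes that promote ferroptosis, 5 rose and 9 fell in Huh7-labelled libraries (5 and 9 adjusted over the list alone; camera adjusted p = 0.460), and 4 rose and 8 fell in HepG2-labelled libraries (6 and 8 adjusted over the list alone; camera adjusted p = 0.695). Of 11 transcript markers of ferroptosis, 6 rose and 2 fell in Huh7-labelled libraries (6 and 2 adjusted over the list alone). The marker list median was 1.18 (camera adjusted p = 0.0134, adjusted p = 0.679 with an estimated correlation). That call was lost without the third treated library (adjusted p = 0.125), and the members that rose, such as CHAC1, ATF3, DDIT3 and SESN2, are also targets of the transcription factor ATF4. In HepG2-labelled libraries 3 markers rose and 1 fell (3 and 1 adjusted over the list alone; camera adjusted p = 0.589). Without the third treated Huh7-labelled library, 4 restraining genes rose and 11 fell in Huh7-labelled libraries. In HepG2-labelled libraries, whose tests share its spread, 5 restraining genes then rose and 16 fell, 8 promoting genes rose and 10 fell, and 4 markers rose and 4 fell.

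In Huh7-labelled libraries large rises with geniposide were in stress-response genes, and large falls were in chaperone and cholesterol genes. The stress-induced transcription factors ATF3, DDIT3 and JUN rose from 10.6 ± 1.03 to 121 ± 64.6, from 3.41 ± 0.371 to 20.1 ± 1.69 and from 113 ± 3.35 to 450 ± 141 FPKM (adjusted p = 1.63e-05, 1.01e-06 and 3.23e-05). CHAC1 rose from 4.56 ± 1.98 to 49.0 ± 27.9 FPKM (3.09 ± 0.33, adjusted p = 7.83e-05), the mTORC1 inhibitor DDIT4 from 27.2 ± 3.02 to 226 ± 93.7 FPKM (adjusted p = 2.80e-05), and CTH, which makes cysteine, from 16.3 ± 0.929 to 78.7 ± 53.3 FPKM (adjusted p = 0.000851). TXNIP, a thioredoxin-binding protein induced by glucose, rose from 7.51 ± 0.942 to 69.3 ± 10.4 FPKM (3.04 ± 0.11, adjusted p = 1.82e-07). The activin subunit INHBE and the dehydrogenase DHRS2 owed much of their rise to the third treated library. INHBE had 2.35, 2.91 and 26.2 FPKM in the treated libraries (2.26 ± 0.61, adjusted p = 0.0149, but 0.116 in a fit of that line alone and 0.0639 with voom on the recovered fragments), and DHRS2 had 3.84, 4.23 and 30.6 FPKM (2.10 ± 0.55, adjusted p = 0.0132, but 0.112 in a fit of that line alone). Without that library the change of DHRS2 was 1.22 (adjusted p = 4.67e-06).

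The inducible HSP70 gene HSPA1B fell from 131 ± 13.3 to 15.1 ± 1.25 FPKM (−3.03 ± 0.09, adjusted p = 1.13e-07) and its near-identical copy HSPA1A from 14.3 ± 2.77 to 0.934 ± 0.145 FPKM (−2.97 ± 0.11, adjusted p = 3.00e-07). Fragments of these copies can be split between them by the counting, so their separate levels are uncertain. The constitutive chaperones HSPA8 and HSP90AA1 fell from 256 to 79.0 FPKM and from 387 to 153 FPKM (adjusted p = 3.04e-07 and 2.57e-05). INSIG1, which restrains sterol synthesis, and HMGCS1, an early enzyme of that pathway, fell from 46.0 ± 1.77 to 15 ± 5.66 and from 22.5 ± 0.303 to 7.10 ± 0.802 FPKM (adjusted p = 0.000262 and 1.01e-06). The cell cycle gene CCND1 fell from 25.2 ± 1.15 to 8.68 ± 1.92 FPKM (adjusted p = 1.48e-05), the carbonic anhydrase CA2 from 148 ± 2.43 to 46.9 ± 4.76 FPKM (adjusted p = 5.35e-07), the RNase P subunit POP1 from 10.8 to 3.25 FPKM (adjusted p = 1.38e-05) and the junction protein AMOT from 142 to 52.9 FPKM (adjusted p = 6.73e-05). In all, 5357 of 15518 tested genes (34.5%) changed in limma's test at an adjusted p under 0.05, 2545 up and 2812 down, and 218 of them by at least 2-fold (140 up, 78 down). A fit of this line alone, which leaves out the spread of the HepG2-labelled libraries, called 3266. The share of rises depended on the scaling: 47.5% as deposited, 61.6% with TPM, 64.0% with TPM and the filter applied afterwards, and 61.2% with the recovered fragments as denominator. Median-of-ratios factors gave 55.5%, and a filter of 5 FPKM gave 38.8%.

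As groups, targets of ATF4, the transcription factor of the integrated stress response, rose in Huh7-labelled libraries by camera at the preset correlation, and 8 lists fell. Of these, the mitosis list alone held with an estimated correlation. Of 38 tested ATF4 targets 30 rose and 1 fell (33 and 1 adjusted over the list alone). The ATF4 target median was 0.94 (camera adjusted p = 2.46e-16, adjusted p = 0.557 with an estimated correlation). They include the glycoprotein hormone STC2, from 17.6 ± 1.54 to 58.9 ± 9.98 FPKM, the glycine transporter SLC6A9, from 4.33 to 10.8 FPKM, and the mTORC1 inhibitor SESN2, from 38.1 to 87.0 FPKM. The third treated library stood apart here: its median over the list was 1.39 above untreated, against 0.64 and 0.74 in the other treated libraries, and without it the median change was 0.68 with 32 rises and 3 falls (camera adjusted p = 1.05e-14, adjusted p = 0.174 with an estimated correlation). Of 20 heat shock proteins 16 fell and 0 rose (18 and 0 adjusted over the list alone). The heat shock median was −0.61 (camera adjusted p = 4.43e-11, adjusted p = 0.0784 with an estimated correlation). Among these were the co-chaperonin HSPE1 (27.3 to 12.5 FPKM) and HSPH1 (29.8 to 11.5 FPKM). Of 33 genes of mitosis 23 fell and 0 rose (24 and 0 adjusted over the list alone). The mitosis list median was −0.33 (camera adjusted p = 1.17e-10, adjusted p = 0.0281 with an estimated correlation). Examples are the mitotic kinases PLK1 (38.5 ± 0.822 to 23.3 ± 0.569 FPKM) and AURKA (27.0 ± 0.940 to 15.1 ± 1.10 FPKM). Of 31 ribosome biogenesis genes and MYC targets, tested as a single list, 23 fell and 0 rose (24 and 0 adjusted over the list alone). The ribosome biogenesis median was −0.38 (camera adjusted p = 3.40e-08, adjusted p = 0.557 with an estimated correlation, and 0.0287 without the third treated library), with NCL, nucleolin, going from 183 ± 2.26 to 108 ± 3.13 FPKM. Of 25 cholesterol synthesis genes 17 fell and 1 rose (17 and 1 adjusted over the list alone). The cholesterol synthesis median was −0.41 (camera adjusted p = 5.35e-05, adjusted p = 0.631 with an estimated correlation). The sterol dehydrogenase NSDHL went from 30.9 to 13.8 FPKM. The third treated library lay lower here too, at −0.73 against −0.29 and −0.31, and without it the median was −0.26, with 17 falls and 3 rises.

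Lists with smaller changes in Huh7-labelled libraries concerned redox enzymes, mitochondria and Wnt signalling. Of 17 genes against superoxide and peroxide 9 fell and 2 rose (11 and 2 adjusted over the list alone). The peroxide defence median was −0.29 (camera adjusted p = 0.00479, adjusted p = 0.557 with an estimated correlation). The peroxiredoxin PRDX1 went from 200 ± 8.34 to 86.4 ± 18.6 FPKM and thioredoxin, TXN, from 239 ± 9.46 to 146 ± 3.97 FPKM. Of 13 mRNAs encoded in mitochondria 7 fell and 0 rose (7 and 0 adjusted over the list alone). The mitochondrial mRNA median was −0.27 (camera adjusted p = 0.000867, adjusted p = 0.562 with an estimated correlation), and MT-ND2 went from 1579 ± 67.8 to 745 ± 49.3 FPKM. Of 42 nuclear genes of oxidative phosphorylation 19 fell and 1 rose (19 and 1 adjusted over the list alone). The oxidative phosphorylation median was −0.18 (camera adjusted p = 0.000648, adjusted p = 0.631 with an estimated correlation). Quantile normalization ended these 3 calls (adjusted p = 0.117, 0.104 and 0.170). Of 16 Wnt targets 7 fell and 1 rose (7 and 1 adjusted over the list alone). The Wnt target median was −0.28 (camera adjusted p = 0.00522, adjusted p = 0.589 with an estimated correlation), and the median was −0.15 without the third treated library. Glycolysis and HIF1 targets did not pass (5 rose and 1 fell of 30, the same adjusted over the list alone; camera adjusted p = 0.149), with treated libraries at medians of 0.40, 0.47 and −0.44. Without the third of these, 23 rose and 2 fell (camera adjusted p = 1.08e-09, adjusted p = 0.278 with an estimated correlation). Leaving it out also brought 3 other lists past camera's threshold, none of them with an estimated correlation. Genes of the unfolded protein response went from 7 rises and 7 falls of 27 (7 and 8 adjusted over the list alone; camera adjusted p = 0.459) to 7 and 19 (adjusted p = 0.000491, and adjusted p = 0.262 with an estimated correlation). G1/S genes went from 5 rises and 11 falls of 35 (6 and 11 adjusted over the list alone; camera adjusted p = 0.0620) to 7 and 18 (adjusted p = 0.00484, and adjusted p = 0.313 with an estimated correlation). Immediate early genes went from 11 rises and 6 falls of 28 (11 and 6 adjusted over the list alone; camera adjusted p = 0.0819) to 12 and 6 (adjusted p = 0.0486, and adjusted p = 0.401 with an estimated correlation).

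**Figure D3:**
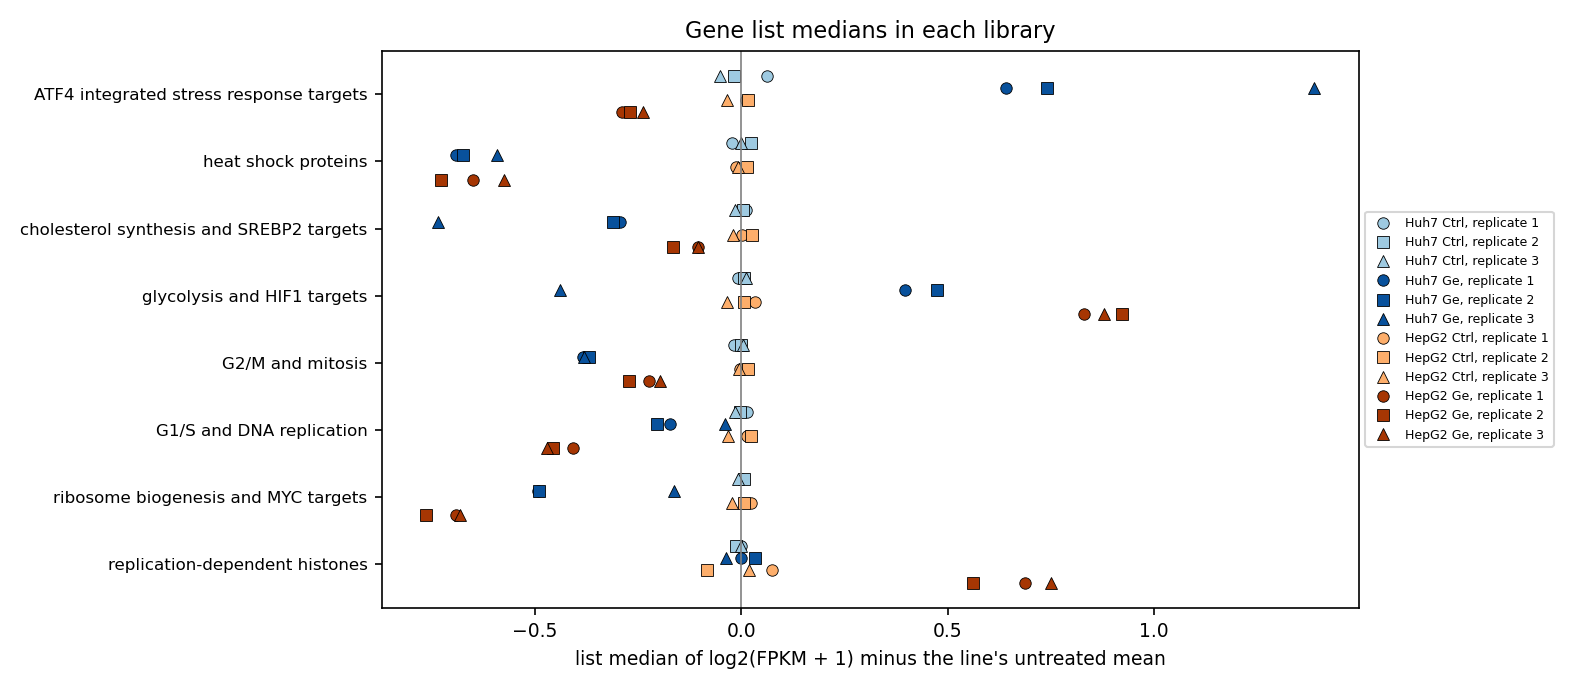
Median log2(FPKM + 1) of 8 fixed gene lists in each library, relative to the mean of the 3 untreated libraries with the same label. Untreated libraries lie near 0; for ATF4 targets the treated Huh7-labelled libraries lie at 0.64, 0.74 and 1.39, and for glycolysis and HIF1 targets at 0.40, 0.47 and −0.44.

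In HepG2-labelled libraries the largest rises with geniposide included those of TXNIP, NDUFA4L2 and CA9, and the largest falls those of KLHL4, GAL and KRT7. TXNIP rose from 41.1 ± 2.02 to 227 ± 4.73 FPKM (2.44 ± 0.11, adjusted p = 1.19e-07). The hypoxia-induced genes CA9, a carbonic anhydrase, and NDUFA4L2, a mitochondrial protein, rose from 106 ± 8.14 to 461 ± 22.9 and from 31.3 ± 2.28 to 166 ± 6.24 FPKM (adjusted p = 1.67e-08 and 1.65e-06). The plasma protease inhibitor A2M rose from 1.59 ± 0.177 to 10.3 ± 0.849 FPKM (adjusted p = 5.23e-08), the copper-carrying ferroxidase CP from 2.93 ± 0.297 to 14.2 ± 0.631 FPKM (adjusted p = 4.55e-08) and the circadian repressor NR1D1 from 4.73 ± 0.339 to 21.2 ± 0.360 FPKM (adjusted p = 8.61e-08). The betaine transporter SLC6A12, the cytokine receptor subunit IL3RA and the keratinocyte protease CASP14 also rose, to 6.51, 5.33 and 4.43 FPKM (adjusted p = 2.87e-07, 4.30e-06 and 1.83e-05). KLHL4, a kelch protein, fell from 17 ± 0.348 to 1.2 ± 0.0393 FPKM (−3.03 ± 0.06, adjusted p = 4.40e-10). The epithelial keratin KRT7 fell from 279 ± 6.60 to 72.9 ± 1.58 FPKM (adjusted p = 8.14e-10), the neuropeptide GAL from 68.0 ± 4.85 to 16.2 ± 2.80 FPKM (adjusted p = 4.29e-07), the vasoactive peptide EDN2 from 16.9 to 4.03 FPKM (adjusted p = 9.34e-08) and CHAC2, a relative of CHAC1, from 13.6 ± 0.741 to 3.07 ± 0.156 FPKM (adjusted p = 7.06e-05). ANKRD2, TNNC1, SEMA6B, SDF2L1 and AP1M2 fell by 1.73 to 2.09 on the log2 scale, and the change of ANKRD2 was −3.43 with TPM scaling.

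Of 15518 genes, 6602 (42.5%) changed in HepG2-labelled libraries, 3258 up and 3344 down, and 438 by at least 2-fold (263 up, 175 down). A fit of this line alone, which leaves out the spread of the Huh7-labelled libraries, called 7692. The share of rises was 49.3% as deposited, 58.0% with TPM and 59.3% with TPM and the filter applied afterwards. With a filter of 5 FPKM this share was 43.0%. Of 30 glycolysis and HIF1 targets 20 rose and 0 fell (25 and 0 adjusted over the list alone). The glycolysis and HIF1 median was 0.88 (camera adjusted p = 8.90e-08, adjusted p = 0.460 with an estimated correlation). Without the third treated Huh7-labelled library 29 rose and 1 fell. Members that rose include the glycolytic enzyme GPI (132 ± 3.14 to 258 ± 2.27 FPKM), hexokinase HK2 (42.4 to 69.9 FPKM) and the oxidase ERO1A (31.5 to 55.5 FPKM). Of 28 immediate early genes 19 rose and 2 fell (19 and 2 adjusted over the list alone). The immediate early median was 0.57 (camera adjusted p = 1.80e-05, adjusted p = 0.0659 with an estimated correlation). Examples are EGR1 (1.64 to 6.12 FPKM) and NR4A2 (2.24 to 5.42 FPKM). Of 19 replication-dependent histone genes, whose mRNAs normally lack a poly(A) tail, 15 rose and 0 fell (15 and 0 adjusted over the list alone; camera adjusted p = 4.46e-05, adjusted p = 0.0659 with an estimated correlation), with H4C3 going from 0.685 ± 0.721 to 4.90 ± 0.472 FPKM. Of 13 NF-kB genes 8 rose and 1 fell (8 and 1 adjusted over the list alone). The NF-kB median was 0.48 (camera adjusted p = 0.00127, adjusted p = 0.231 with an estimated correlation). Among these were the inhibitor NFKBIA (36.5 to 65.3 FPKM) and SOD2 (6.10 to 11.9 FPKM). Of 26 type I interferon genes 15 rose and 4 fell (15 and 4 adjusted over the list alone). The interferon median was 0.40 (camera adjusted p = 0.00705, adjusted p = 0.274 with an estimated correlation), with IFI6 going from 10.9 ± 0.957 to 43.0 ± 4.82 FPKM and OAS1 from 5.23 to 11.4 FPKM. Of 9 STAT3 genes 6 rose and 1 fell (6 and 1 adjusted over the list alone; camera adjusted p = 0.00491, adjusted p = 0.171 with an estimated correlation), and of 9 genes of gluconeogenesis and glycogen 6 rose and 0 fell (6 and 0 adjusted over the list alone; camera adjusted p = 0.0107, adjusted p = 0.213 with an estimated correlation), such as the branching enzyme GBE1 (31.6 to 69.9 FPKM). Without the third treated Huh7-labelled library 7 of the latter rose and 1 fell.

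The lists that fell in HepG2-labelled libraries concerned growth, mitochondria, chaperones and glutathione. Of 31 ribosome biogenesis genes and MYC targets 26 fell and 1 rose (28 and 1 adjusted over the list alone). The ribosome biogenesis median was −0.68 (camera adjusted p = 2.76e-10, adjusted p = 0.213 with an estimated correlation). Members that did so include the spermidine synthase SRM (90.0 ± 1.90 to 35.4 ± 2.92 FPKM) and BOP1 (40.9 to 20.8 FPKM). Of 35 G1/S genes 28 fell and 2 rose (29 and 2 adjusted over the list alone). The G1/S median was −0.44 (camera adjusted p = 1.76e-09, adjusted p = 0.0659 with an estimated correlation), with the DNA methylation cofactor UHRF1 going from 37.9 ± 0.383 to 16.2 ± 0.277 FPKM and the replication factor CDC45 from 22.2 to 11.4 FPKM. Of 33 mitosis genes 18 fell and 1 rose (20 and 1 adjusted over the list alone). The mitosis list median was −0.21 (camera adjusted p = 0.000264, adjusted p = 0.112 with an estimated correlation), and 22 fell and 2 rose without the third treated Huh7-labelled library. Of 20 heat shock proteins 19 fell and 0 rose (19 and 0 adjusted over the list alone). The heat shock median was −0.65 (camera adjusted p = 1.76e-09, adjusted p = 0.0659 with an estimated correlation). Of 42 nuclear oxidative phosphorylation genes 28 fell and 0 rose (32 and 0 adjusted over the list alone). The oxidative phosphorylation median was −0.40 (camera adjusted p = 1.76e-09, adjusted p = 0.213 with an estimated correlation), with the ATP synthase subunit ATP5MC1 going from 46.9 ± 2.25 to 14.9 ± 1.16 FPKM. Of 13 mitochondrially encoded mRNAs 10 fell and 0 rose (10 and 0 adjusted over the list alone). The mitochondrial mRNA median was −0.72 (camera adjusted p = 0.000153, adjusted p = 0.231 with an estimated correlation). Of 27 selenoproteins and glutathione enzymes 11 fell and 0 rose (11 and 0 adjusted over the list alone). The selenoprotein median was −0.22 (camera adjusted p = 0.0217, adjusted p = 0.293 with an estimated correlation). None of the 15 lists past camera in HepG2-labelled libraries held with an estimated correlation. ATF4 targets did not pass there (7 rose and 14 fell of 38, the same adjusted over the list alone; median −0.29, camera adjusted p = 0.140), though without the third treated Huh7-labelled library, whose values enter the shared spread, the list passed as lower (adjusted p = 0.0451, but adjusted p = 0.719 with an estimated correlation). The unfolded protein response (3 rose and 8 fell of 27, the same adjusted over the list alone; camera adjusted p = 0.140) and autophagy and lysosome genes (13 rose and 5 fell of 33, the same adjusted over the list alone; camera adjusted p = 0.139) likewise passed without that library, with 6 rises and 17 falls, and 18 rises and 9 falls (adjusted p = 0.0130 and 0.0321). Neither did so with an estimated correlation (adjusted p = 0.374 and 0.402 with an estimated correlation).

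Other lists passed in neither line. Of 29 targets of the antioxidant regulator NRF2, 1 rose and 9 fell in Huh7-labelled libraries (1 and 9 adjusted over the list alone; camera adjusted p = 0.239), and 8 rose and 14 fell in HepG2-labelled libraries (8 and 15 adjusted over the list alone; camera adjusted p = 0.354). In the latter the reductase AKR1C1 rose by 1.37 ± 0.07 (adjusted p = 3.95e-07) and the epoxide hydrolase EPHX1 by 1.03 ± 0.07 (adjusted p = 1.63e-06). Of 25 p53 targets 9 rose and 3 fell in Huh7-labelled libraries (9 and 4 adjusted over the list alone; camera adjusted p = 0.149), with GADD45A up by 1.66 ± 0.12 (adjusted p = 7.51e-06), and 3 rose and 6 fell in HepG2-labelled libraries (3 and 6 adjusted over the list alone; camera adjusted p = 0.826). Of 22 iron homeostasis genes 2 rose and 3 fell in the former (2 and 2 adjusted over the list alone; camera adjusted p = 0.981), and 5 rose and 6 fell in the latter (5 and 6 adjusted over the list alone; camera adjusted p = 0.783). Of 29 apoptosis regulators 5 rose and 6 fell (5 and 6 adjusted over the list alone; camera adjusted p = 0.920) and 7 rose and 10 fell (8 and 10 adjusted over the list alone; camera adjusted p = 0.935). The pro-apoptotic gene BBC3 rose in both, by 1.06 ± 0.16 and 1.0 ± 0.16 (adjusted p = 0.000561 and 0.000475). Of 58 cytosolic ribosomal protein genes 6 rose and 6 fell (5 and 5 adjusted over the list alone; camera adjusted p = 0.944) and 5 rose and 5 fell (1 and 3 adjusted over the list alone; camera adjusted p = 0.826). Of 7 fibroblast markers 2 rose and 0 fell (2 and 0 adjusted over the list alone; camera adjusted p = 0.478) and 5 rose and 1 fell (5 and 1 adjusted over the list alone; camera adjusted p = 0.0743). Several of these counts moved without the third treated Huh7-labelled library. In Huh7-labelled libraries 3 NRF2 targets then rose and 12 fell, 9 p53 targets rose and 6 fell, 3 iron genes rose and 5 fell, 18 ribosomal protein genes rose and 7 fell, and 3 fibroblast markers rose and 1 fell. In HepG2-labelled libraries 5 p53 targets rose and 8 fell, 11 ribosomal protein genes rose and 9 fell, and 5 fibroblast markers rose and 2 fell.

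The response to geniposide differed between the lines most in ATF4 targets. Of 38 tested targets 30 had a lower response in HepG2-labelled than in Huh7-labelled libraries and 0 a higher one (32 and 0 adjusted over the list alone; camera adjusted p = 5.52e-16, adjusted p = 0.319 with an estimated correlation). CHAC1 differed by −3.57 ± 0.47 (adjusted p = 0.000447), ATF3 by −3.16 ± 0.38 (adjusted p = 0.000283) and DDIT4 by −2.70 ± 0.37 (adjusted p = 0.000605). PSAT1, a serine synthesis enzyme, rose from 142 ± 5.92 to 298 ± 91.3 FPKM in Huh7-labelled libraries and fell from 76.0 ± 2.35 to 27.6 ± 2.55 FPKM in HepG2-labelled libraries (−2.46 ± 0.23, adjusted p = 5.90e-05). DUSP5, a phosphatase of ERK, went the opposite way, from 5.82 ± 0.163 to 3.02 ± 0.370 and from 7.15 ± 0.578 to 21.5 ± 0.934 FPKM (2.23 ± 0.11, adjusted p = 1.50e-06). HSPA1A and HSPA1B fell further in Huh7-labelled libraries (2.54 ± 0.16 and 2.44 ± 0.13). A2M differed by 2.11 (adjusted p = 2.03e-06), CA9 by 2.12 (adjusted p = 6.16e-07) and KLHL4 by −3.0 (adjusted p = 1.89e-08), and the calls of CA9 and KLHL4 were lost with voom on the recovered fragments (adjusted p = 0.109 and 0.0920). SLC7A11 differed by −2.11 ± 0.30 (adjusted p = 0.000725), PTGS2 by 2.03 ± 0.13 (adjusted p = 5.58e-06), ACSL4 by 0.53 ± 0.07 (adjusted p = 0.000474) and FTH1 by 0.31 ± 0.10 (adjusted p = 0.0364). In limma's test of this difference 4317 genes passed, 2195 higher and 2122 lower in HepG2-labelled libraries (6533 passed with sample weights), and the share of higher ones was 50.8% as deposited and 40% with the recovered fragments as denominator.

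Changes shared by both lines were tested as an overlap. TXNIP and VEGFA, an angiogenic factor induced by hypoxia, rose in both, VEGFA from 4.65 to 10.3 and from 31.2 to 88.3 FPKM (0.99 ± 0.05 and 1.47 ± 0.05, adjusted p = 1.01e-06 and 3.19e-08). The RNA helicase DHX9 fell from 80.5 to 35.9 and from 65.5 to 27.8 FPKM (−1.14 ± 0.05 and −1.21 ± 0.05), the cold-induced RNA-binding protein RBM3 by 1.22 and 1.27, the splicing factor SRSF3 by 1.16 and 1.12, the proteasome subunit PSMD1 by 1.01 and 1.15, and NCL by 0.75 and 0.68 on the log2 scale. Of 2849 genes changed in both lines 2401 (84.3%) changed the same way and 448 the opposite way. The number changed the same way was 3726 without the third treated Huh7-labelled library and 3882 with sample weights. Rises in both numbered 966 against 534 expected of independent lists (Fisher's exact test, one-sided, p = 1.46e-104), and falls in both 1435 against 606, 2.37 times as many. That test takes genes as independent units, so its p does not measure the spread between libraries. The tested genes also include some expressed under a single label, which can make the expected numbers too low. The share of rises among shared changes was 40.2% as deposited, 58.3% with TPM, 58.4% with TPM and the filter applied afterwards, 52.1% with median-of-ratios factors and 52.3% with the recovered fragments as denominator. A filter of 5 FPKM gave 34.1%. Across all tested genes the changes correlated with Pearson's r = 0.342 and Spearman's rho = 0.361, and genes are not independent replicates.

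More genes differed between the untreated lines than changed with geniposide in either. In HepG2-labelled libraries the alkaline phosphatases ALPI and ALPP stood at 1039.9 ± 45.0 and 394 ± 12.1 FPKM, the calcium-binding protein S100A6 at 473 ± 15.7 FPKM and KRT7 at 279 ± 6.60 FPKM, with 0 fragments in all 3 untreated Huh7-labelled libraries. Against the level of 3 fragments per library these are at least 15420-fold, 6796-fold, 2585-fold and 6430.4-fold higher. ALPI and ALPP are close copies and the split between them is uncertain. The serine protease PRSS56 stood at 446 ± 25.0 against 0.0584 FPKM. In Huh7-labelled libraries the insulin receptor substrate IRS4 (219 ± 8.53 FPKM), AMOT (142 ± 1.88 FPKM) and the neuronal ubiquitin hydrolase UCHL1 (82.6 ± 3.85 FPKM) stood against 0 fragments, CA2 at 148 ± 2.43 against 0.0327 FPKM, and the basement membrane protein NID1 at 52.9 ± 1.55 against 0.00375 FPKM. NRF2 targets were higher in HepG2-labelled libraries for 27 of 29 tested members and lower for 0 (27 and 0 adjusted over the list alone). The NRF2 median was 1.07 (camera adjusted p = 3.01e-07, adjusted p = 0.0494 with an estimated correlation). Iron homeostasis genes were higher for 16 of 22 and lower for 1 (16 and 1 adjusted over the list alone). The iron median was 0.91 (camera adjusted p = 0.000309, adjusted p = 0.0494 with an estimated correlation). Of the other lists, 6 held at the same adjusted p of 0.0494 with an estimated correlation. Fibroblast markers were higher for 7 of 7 (median 2.20), histones for 18 of 19 (19 adjusted over the list alone) and STAT3 genes for 8 of 9. Immediate early genes were higher for 22 and lower for 5 of 28, epithelial junction genes for 13 and 3 of 18, and Hippo targets for 14 and 2 of 18. Counts adjusted over the list alone did not differ but for the histones. In limma's test 11146 genes differed, 5595 higher and 5551 lower in HepG2-labelled libraries, and 7220 differed among the fewer genes left by a filter of 5 FPKM. The share higher was 50.2% as deposited, 36.6% with TPM, 36.5% with the recovered fragments as denominator and 34.5% with TPM and the filter applied afterwards, where the median of all genes shifted to −0.27, −0.23 and −0.30.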

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

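The scaling and the GC content and length tests of the ATF4 targets and the depth test of the low-level transcripts were set before their results were seen; the tests of the third library, the other tests of the low-level transcripts, and the counts over other splits of the samples were chosen after.

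The response to geniposide differed between HepG2-labelled and Huh7-labelled libraries, by a test of the difference itself, in 15 of the fixed lists at camera's preset correlation. None of the 15 held with an estimated correlation (lowest adjusted p = 0.211, for the histones). The median log2 difference was −1.27 for ATF4 targets. Lists with a higher response in HepG2-labelled libraries were glycolysis and HIF1 targets (0.68, camera adjusted p = 4.76e-05), replication-dependent histones (0.61, adjusted p = 0.000264), NF-kB genes (0.49, adjusted p = 0.00227), cholesterol synthesis (0.43, adjusted p = 0.00302), gluconeogenesis and glycogen (0.43, adjusted p = 0.00302), immediate early genes (0.41, adjusted p = 0.0276), type I interferon genes (0.30, adjusted p = 0.00227), Wnt targets (0.29, adjusted p = 0.0112), autophagy and lysosome genes (0.22, adjusted p = 0.0137) and mitosis (0.20, adjusted p = 0.0124). Lists with a lower one were ribosome biogenesis and MYC targets (−0.33, adjusted p = 0.00798), G1/S genes (−0.32, adjusted p = 2.09e-05), Hippo targets (−0.21, adjusted p = 0.0260) and nuclear oxidative phosphorylation (−0.18, adjusted p = 0.00245). Without the third treated Huh7-labelled library the medians of glycolysis and cholesterol both became 0.27, that of Wnt targets 0.19 and that of ribosome biogenesis −0.20, and the immediate early list no longer passed (adjusted p = 0.127). Quantile normalization ended the call of Hippo targets (adjusted p = 0.141).

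Among single genes the same test picked out HSPA1A (2.54), HSPA1B (2.44), DUSP5 (2.23), CA9 (2.12), A2M (2.11), PTGS2 (2.03), ACSL4 (0.53) and FTH1 (0.31) with a higher log2 response in HepG2-labelled libraries. CHAC1 (−3.57), ATF3 (−3.16), KLHL4 (−3.0), DDIT4 (−2.70), PSAT1 (−2.46) and SLC7A11 (−2.11) had a lower one, and so differed 174 other named genes in either direction.

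ATF4 targets rose in Huh7-labelled and not in HepG2-labelled libraries. The third treated Huh7-labelled library alone is argued against, since without it the median over the 38 targets was still 0.68. With the recovered fragments as denominator the difference in list medians was −1.29, beside −1.23 as deposited. That test cannot decide on scaling, since the swap moves the treated and untreated libraries of a line almost alike. The deposited totals were 1.09 to 1.10 (untreated) and 1.15 to 1.17 (treated) times the recovered sums for Huh7, and 0.895 to 0.912 and 0.909 to 0.914 for HepG2. Over all 15518 tested genes the median difference was 0.00173 as deposited, so the difference of these targets was not a shift of all genes alike. A trend with GC content or gene length is argued against by −1.20 after both were removed from each library. A difference between the cells in the integrated stress response may therefore be followed up as a hypothesis, on the limit that the set test lost its call with an estimated correlation (adjusted p = 0.319). What separates the cells, and whether nutrients in the medium ran low to a different extent, was not tested.

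Transcripts at low level were more often called higher than lower with geniposide: among 20180 genes below the filter with a fragment in some library, a fit without the filter called 612 higher and 210 lower in Huh7-labelled libraries, and 463 higher and 218 lower in HepG2-labelled libraries, DUOX1 being among the former in both, and every treated library held a larger share of lncRNA fragments than any untreated one of its line (1.88 to 2.08% against 1.71 to 1.77% for Huh7, 1.48 to 1.51% against 1.12 to 1.18% for HepG2). A difference in depth is argued against, because with all libraries thinned to 15056655 fragments the lowest treated library still had 153 more genes with 3 fragments than the highest untreated one in HepG2-labelled libraries, and 195 more in Huh7-labelled libraries. A uniform background of genomic fragments is argued against by genes at 0 in untreated libraries, whose mean gain was at most 0.0912 times the gain of genes at 0.1 to 1 FPKM. One factor per library is argued against by the ratio of summed levels of genes at 0.1 to 1 FPKM to those over 100 FPKM, where the lowest treated library was at least 1.10 times the highest untreated one. Summed over protein-coding genes at 0.1 to 1 FPKM, levels were 1.17 (Huh7) and 1.12 (HepG2) times as high with geniposide. For those over 100 FPKM the sums were 0.887 and 0.921 times as high, and for those at 10 to 100 FPKM 0.925 and 0.935 times. The ratio above rises with either change, so it does not separate a rise of low-level transcripts from a fall of abundant ones. The low-level sum does not show whether DUOX1, at 3.33 and 3.11 times, stands out among single genes. The source of its rise and of the changes in these sums was not tested.

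Other splits of the same libraries into groups of 3 were too few for a share under 0.05 within a line. The real split gave 5357 changed genes in Huh7-labelled libraries (highest other split 2; 1 of 10 splits gave as many), 6602 in HepG2-labelled libraries (highest other 1; 1 of 10) and 11146 between the untreated lines (highest other 1; 1 of 10). Counts of lists past camera did not set the real split apart: 10 lists in Huh7-labelled libraries against a highest other of 10 (2 of 10 splits), and 15 in HepG2-labelled libraries against 13 (1 of 10). Every other split of this kind kept more libraries of one real group on one side. Part of the real difference thus stayed in its contrast, and the rest entered the spread between libraries. Such splits are no baseline without an effect, for counts of genes or of lists. For genes changed the same way in both lines (2401; 1 of 100 splits) and for the difference between lines (4317; 2 of 100 splits) they do not decide, since splits within the lines test for no effect in either line, and not for independent or equal effects. The highest other counts, 448 and 7580, are those of a swap of treated and untreated libraries within one line, which turns opposite changes into shared ones and the difference of the effects into their sum.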

How the results depend on the processing

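Voom, the recovered-fragment denominator and the lists without a library were chosen after the data were seen. So was keeping the filter on the deposited FPKM under the rescalings, which were first run with a later filter. The correlation of changes and the DUOX1 changes in both lines stayed above 0 under every setting run. The other results are counts, which have no direction, and the balance of rises and falls turned with TPM: rises were 61.6% against 47.5% as deposited (Huh7) and 58.3% against 40.2% (changed the same way in both). Of 9633 values of named genes (389 gene and comparison pairs, 367 past the threshold) 9426 kept their side of the threshold (14 of these changed sign with no call in either fit), 187 lost the call, 19 gained it and 1 reversed: PYGL in Huh7-labelled libraries (0.00879 with quantile normalization, adjusted p = 0.909). Most of these genes were named for large changes or small p-values in the main fit, so the share kept does not carry over to calls in general. A minimum change of 2-fold left 218 genes (Huh7), 438 (HepG2), 466 (difference), 4139 (untreated lines) and 38 (same way in both), by its construction. A 5 FPKM filter left 7220 for the untreated lines because fewer genes were tested. Sample weights gave 6533 for the difference and 3882 for the overlap, and a fit within the line gave 3266 for Huh7; the cause was not tested. The correlation of changes became 0.274 with voom and 0.244 with TPM and a later filter, over 21135 genes; the cause was not tested. With an estimated correlation 1 list (Huh7) and 0 lists (HepG2) passed, against 20 and 29 with fry, which does not compare a list with other genes.

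Leaving out each library in turn gave 4098 to 7049 genes (Huh7), 5406 to 8330 (HepG2), 3333 to 6098 (difference), 10398 to 11995 (untreated lines), 1926 to 3726 (overlap; highest without treated Huh7-labelled library 3), 10 to 13 and 14 to 18 lists, r of 0.303 to 0.389, and DUOX1 changes of 0.22 to 0.29 (Huh7) and 0.47 to 0.54 (HepG2). INHBE has no value without any of the treated Huh7-labelled libraries, since it then fails the filter. The shared replicate numbers do not pair the samples (correlations of same-numbered deviations −0.0615 to 0.0201). With the replicate block 4520, 5952, 3160 and 1994 genes passed (Huh7, HepG2, difference, overlap), and DUOX1 in Huh7-labelled libraries, at 0.26, lost its call (adjusted p = 0.0797), with fewer residual degrees of freedom by construction. Depth limits genes such as DUOX1, where 3 fragments are worth 0.0187 to 0.0231 FPKM.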

Other observations

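All tests in this part were chosen after the result was seen.

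Many genes of RNA splicing and of the proteasome were lower with geniposide. These families were chosen after their members' values were seen, so their adjusted p values describe them and are no independent test. Of 12 SR splicing factors 10 fell and 0 rose in Huh7-labelled libraries (median −0.54, camera adjusted p = 0.00516 with an estimated correlation), and 8 fell and 2 rose in HepG2-labelled libraries (median −0.39, adjusted p = 0.0895 with an estimated correlation). SRSF3 changed by −1.16 and −1.12, SRSF2 by −1.35 and −1.06, and SRSF1 by −0.96 and −1.24. Of 35 hnRNP genes, pseudogene copies included, 19 fell and 0 rose in Huh7-labelled libraries and 15 fell and 0 rose in HepG2-labelled libraries (adjusted p = 0.00205 and 0.00516 with an estimated correlation). HNRNPM changed by −0.96 and −0.88, and HNRNPD by −1.07 and −0.65. Of 36 proteasome subunits 33 fell and 2 rose in HepG2-labelled libraries (median −0.67, adjusted p = 0.0431 with an estimated correlation), the rises being in PSMB8 (0.41) and PSMB9 (0.33), subunits of the immunoproteasome, while PSMB10, also one of these, fell (−0.42, adjusted p = 0.0339). In Huh7-labelled libraries 18 fell and 0 rose (adjusted p = 0.102 with an estimated correlation), and 29 fell and 1 rose without the third treated library.

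Aminoacyl-tRNA synthetases, several of which are ATF4 targets, fell for 15 of 18 and rose for 1 in HepG2-labelled libraries (median −0.59, adjusted p = 0.102 with an estimated correlation), WARS1 by 1.54 on the log2 scale. In Huh7-labelled libraries 7 rose and 5 fell (adjusted p = 0.600 with an estimated correlation), with SARS1 at 1.0 and CARS1 at 0.80. Of 23 host genes of small nucleolar RNAs, whose spliced transcripts are degraded during translation, 13 rose and 3 fell in Huh7-labelled libraries (median 0.31, adjusted p = 0.0895 with an estimated correlation), and 8 rose and 3 fell in HepG2-labelled libraries (adjusted p = 0.408 with an estimated correlation). SNHG1 changed by 1.67 and 0.69, and SNHG4 by −1.06 and −1.08. No family median changed sign under TPM, median-of-ratios, quantile or recovered-fragment scaling or without the third treated Huh7-labelled library. The families of this paragraph and their named genes were likewise chosen after their values were seen.

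Most transcripts of secreted hepatocyte proteins were near 0 in all 12 libraries, including ALB, TTR, APOB and AFP, which lines of these names are known for. Exceptions include C3 at 27.5 and VTN at 4.78 FPKM in untreated HepG2-labelled libraries. Too little depth is argued against by the level of 3 fragments, whose median over the list was 0.0622 FPKM. Genes left out of the counting are argued against by the 27 of 34 genes that had a fragment in some library. Cells of another lineage than the labels name and loss of liver transcripts in culture cannot be told apart, since either leaves few genes of the list expressed, and 3 of 34 reached 1 FPKM in the untreated libraries of either line; high IRS4 and UCHL1 under the Huh7 label and ALPI, ALPP, KRT7 and S100A6 under the HepG2 label are not typical of liver cells, which loss alone need not bring, but these were picked for their levels and do not decide. An exchange among the 12 columns cannot give transcripts near 0 in all of them, while a mix-up with cells from elsewhere stays open. The comparisons therefore hold as differences between the groups of sequenced libraries, whichever cells they came from. The treatment, like the cell line, is known from the labels alone.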
